A study of Mus musculus with 40 samples.

How the data were processed

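Total RNA of whole mouse spleen was amplified, labelled with Cy3 and hybridised in 1 colour, per the labels' protocols, with 4 arrays in each of 10 groups of genotype and infection. Samples were grouped by their titles, and the series design states that the 4 replicates of a group are independent. Per the file headers, the arrays were of an Agilent mouse design with 62976 spots annotated on mouse build mm9, scanned and extracted with Agilent Feature Extraction. The deposited scanner files hold processed spot intensity, from which the software had already subtracted background, with a multiplicative detrending on some arrays, together with raw median intensity and quality marks, per the file headers. The deposited value table of the series holds log2 values of the same arrays for 20688 features. Set against the scanner values, its columns were differences on a log2 scale centred on each feature's median over the arrays: the correlation across features was 0.484 at the lowest and 0.917 at the median, the slope ran from 0.767 to 0.971, and the direction was the same. Its column medians ran from -0.0879 to 0.192. Its absolute scale and the way it was centred stay unknown, so it served as an alternative only. The submitters' processing notes name limma, with no version, and no further step of theirs is given in the sources used here.

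The main values were made from the processed intensity as follows. Control spots and outlier spots were left out, spots of a probe were averaged, and each array was divided by its 75th percentile, with a floor of 0.01 before taking log2, since some background-subtracted signals lie at or below 0. Values at the floor have no order. Of 59305 spots that are not controls came 55681 probes, of which 26582 (47.7%) had a current gene symbol through a RefSeq table of assembly GRCm38.p6. That table was used only for names and for which genes neighbour each other, and names of the array's design were kept otherwise. A probe was kept if it was well above background on at least 3 of 4 arrays of at least 1 group and had at least 2 values per group. The 42803 kept probes gave 30542 genes tested, 17319 of them with a current symbol. For the 7631 genes with several probes, the probe with the highest mean over all arrays stood for the gene. Where a gene was not well above background on any array of a group, its change is given as at least N-fold: the mean of the bright group against the mean, over the dim group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal. Differences of responses that involve such a group are fitted values and no bounds. Well above background were 60.3% to 83.9% of probes on WT infected, 67.9% to 78.0% on Tlr7KO mock and 63.3% to 70.0% on Myd88KO infected arrays.

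A mean per group was fitted over all 40 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 2.83), so that all groups shared 1 estimate of the spread. Contrasts were infected minus mock in each genotype, differences of these between genotypes, and each mutant's mock group minus WT mock. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast at 0.05. The contrasts, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. On data simulated for the WT infection contrast, with 200 of 30542 genes changed, the fit found 13.4% of 1.5-fold, 22.4% of 2-fold and 83.3% of 4-fold changes with 1 false call. For the difference of Tlr7KO and WT responses it found 0% of 1.5-fold, 10.5% of 2-fold and 54.6% of 4-fold changes with 3 false calls. These rates and false calls need not hold for the real arrays.

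Lists of genes, 29 in all, covered the type I interferon response, the interferon gamma response, interferon genes, inflammatory cytokines, chemokines, NF-kappaB targets, the Toll-like receptor pathway, MHC class I and MHC class II presentation, immediate early genes, heat shock and chaperones, cell cycle, ribosomal proteins, and iron and haem handling. Cell marker lists covered plasmacytoid and conventional dendritic cells, neutrophils, inflammatory monocytes, red pulp and marginal zone macrophages, B cells, plasma cells, T cells, NK and cytotoxic cells, erythroid cells, platelets and megakaryocytes, stroma and endothelium, pancreas and adipose tissue. Members without a tested probe, such as Mx1, Mx2, Il12b, Cxcl11, Tnfaip3 and Ly6g, were left out. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists of a contrast, and again with an estimated correlation. With the estimated correlation 9 of 18 calls held in WT, 5 of 16 in Tlr7KO, 9 of 15 in Tlr9KO, 5 of 13 in Unc93b1 3d and 4 of 17 in Myd88KO, and 0 held in the mock contrasts. A score per array, the mean deviation of a list's genes from their mean over 40 arrays, was compared by an exact two-sided permutation test over 70 assignments. Figures were drawn with matplotlib.

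Whether replicate numbers pair infected and mock arrays was checked in each genotype from the correlation, across genes, of the deviations of same-numbered arrays from their group means. In Unc93b1 3d all 4 pairs lay over 0.1 (0.123 to 0.447) and each infected array correlated best with its own number, the highest mean of 24 possible matchings, so the numbers were taken to pair these arrays and the fit with the replicate number as a block is given beside the main one. Same-numbered arrays of every genotype lay in the same slide column, but the labels name no shared batch or day. The pairing was read from the same data and 1 of the 5 genotypes met it, so it stays uncertain.

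Named genes followed a rule: in WT infection the 12 largest rises and 8 largest falls past the threshold, with every infected array beyond every mock array and a current symbol, and 6 and 4 in each mutant. Each difference of responses gave its 10 largest negative and 5 largest positive values, each mock contrast 5 and 5, and each list up to 4 members with the largest change. The targeted genes and a fixed set of readouts, among them Isg15, Irf7, Cxcl10, Il6, Tnf, Ifng, Ifnb1 and Ifna4, could always be named, and a gene named for 1 contrast could be given in any other. Some named calls rest on an array: leaving out 1 array ended 14 of 100 named calls in WT infection, 10 of 55 in Tlr7KO, 11 of 100 in Tlr9KO, 16 of 29 in Unc93b1 3d and 16 of 45 in Myd88KO, and such genes are named only together with the arrays. Some results that the rule would name are not reported here.

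Alternatives fixed beforehand were quantile normalisation, median centring, the value table of the series, no filter, probes well above background on all 40 arrays, all probes, only the arrays compared, a trended and robust spread, array weights, the replicate number as a block, slide as a block, stricter thresholds, each array left out, and the estimated correlation. The planned normexp correction of mean signals was run on median signals with an offset of 50, since the scanner files used here hold no mean signal column. Floors of 0.005 and 0.02, a covariate of each array's signal distribution (the log2 ratio of its median to its 75th percentile) and leaving out 4 arrays in doubt were chosen after seeing the data.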

Results

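Gene expression was measured in whole spleens of female mice 24 hours after intraperitoneal injection of 1000000 erythrocytes, which were either uninfected (mock) or carried Plasmodium chabaudi, a rodent malaria parasite. Mice of 5 genotypes were used. Wild-type C57BL/6 mice were set beside mice lacking Tlr7, the endosomal receptor for single-stranded RNA (Tlr7KO), and mice lacking Tlr9, the endosomal receptor for DNA with unmethylated CpG motifs (Tlr9KO). The other genotypes carried the 3d allele of Unc93b1, a point mutation in the chaperone that brings nucleic acid-sensing Toll-like receptors to endosomes (Unc93b1 3d), or lacked Myd88, the adaptor used by most Toll-like receptors and by the interleukin-1 receptor family (Myd88KO). Each of the 10 groups held 4 independent replicates, with amplified RNA hybridised in 1 colour to 40 arrays. The series title asks whether Tlr7 is a primary sensor of the infection, and the comparisons follow from that: infected against mock in each genotype, the difference of that response between genotypes, and the mock groups against each other.

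The share of probes well above background, the signal depth of an array, ran from 53.6% to 83.9%, and the 75th percentile of processed signal ran from 419.9 to 1196 intensity units. WT infected replicate 1 had the highest share, 83.9%, and a negative-control median of 48, against 21 to 22 on the WT mock arrays. Each of the 5 slides held the 8 arrays of 1 genotype, so genotype and slide cannot be told apart in comparisons of mock groups. Within every slide, row 1 held the infected and row 2 the mock arrays, so row and infection cannot be told apart either. The slide column followed the replicate number. The scanner software had applied a multiplicative detrending to 4 of 4 Tlr7KO mock, 3 of 4 Tlr7KO infected and 4 of 4 Myd88KO mock arrays, and to 0 of 4 Myd88KO infected arrays and 0 arrays of the other genotypes. Changes are differences of group means on the log2 scale, with the standard error (SE) of the fit, n = 4 per group unless stated, and Benjamini-Hochberg adjusted p-values from limma. The number of arrays limits the precision.

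The targeted genes were examined first. The Tlr7 probe lay at 1.07 ± 0.11 (SD, n = 4) on the log2 scale in WT mock spleens and at -5.72 ± 0.69 in Tlr7KO mock spleens, a difference of -6.79 (adjusted p = 4.68e-18). In infected spleens it lay at 2.69 ± 0.23 in WT and at -5.12 ± 0.83 in Tlr7KO (difference -7.81, adjusted p = 5.98e-20), and it was well above background on 0 Tlr7KO arrays, so that it was at least 69.24-fold lower in mock and at least 184.5-fold lower in infected spleens. A second Tlr7 probe, well above background on 1 of 4 Tlr7KO arrays in each condition, gave -5.13 in Tlr7KO mock and -5.38 in Tlr7KO infected spleens, so the Tlr7KO label was borne out by both probes. The Tlr9 probe was not lower in Tlr9KO mice, at 0.62 above WT in mock (adjusted p = 0.0701) and 0.49 above WT in infected spleens (adjusted p = 0.18). The Myd88 probe differed by 0.08 between Myd88KO and WT mock spleens (adjusted p = 0.767), and the Unc93b1 probe by -0.01 between Unc93b1 3d and WT mock spleens (adjusted p = 0.993). Probes can lie outside a deleted part and a point mutation leaves the transcript in place, so the Tlr9, Myd88 and Unc93b1 probes check no label. In infected spleens Myd88 was lower than in WT by -1.60 in Myd88KO (adjusted p = 4.85e-10), and also by -1.53 in Unc93b1 3d and -1.30 in Tlr7KO.

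In WT mice, infection raised interferon genes, chemokines and acute inflammatory mediators within 24 hours. Ifnb1, which encodes interferon beta, rose by 9.30 (SE 0.51, adjusted p = 5.84e-16), and since it was not well above background in mock spleens this stands for an at least 290.3-fold rise. Ifna4 rose by 7.28 (SE 0.44, at least 142-fold, adjusted p = 7.37e-15). The monocyte-attracting chemokines Ccl7, Ccl2 and Ccl12 rose by 8.30 (SE 0.54), 7.36 (SE 0.23) and 7.21 (SE 0.35), the cytokine Il6 by 7.32 (SE 0.30), and Acod1, the enzyme that makes itaconate in activated macrophages, by 7.79 (SE 0.35, adjusted p = 6.54e-18). In WT mock spleens Ccl7 and Acod1 were well above background on 2 of 4 arrays and Il6 on 3 of 4. Of the interferon genes, 12 of 13 measured members rose, with a median change of 5.57, and 13 rose when adjusted over the list alone (camera adjusted p = 1.15e-30). Ifna2, Ifna7 and Ifna5 rose by 7.18 (at least 145.2-fold on its probe), 6.97 and 6.75, and Ifng, the interferon made by natural killer (NK) and T cells, by 4.91 (SE 0.22, adjusted p = 6.54e-18). Interferon alpha genes are near-identical copies and their probes can share signal, so their separate values are uncertain.

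**Figure D1:**
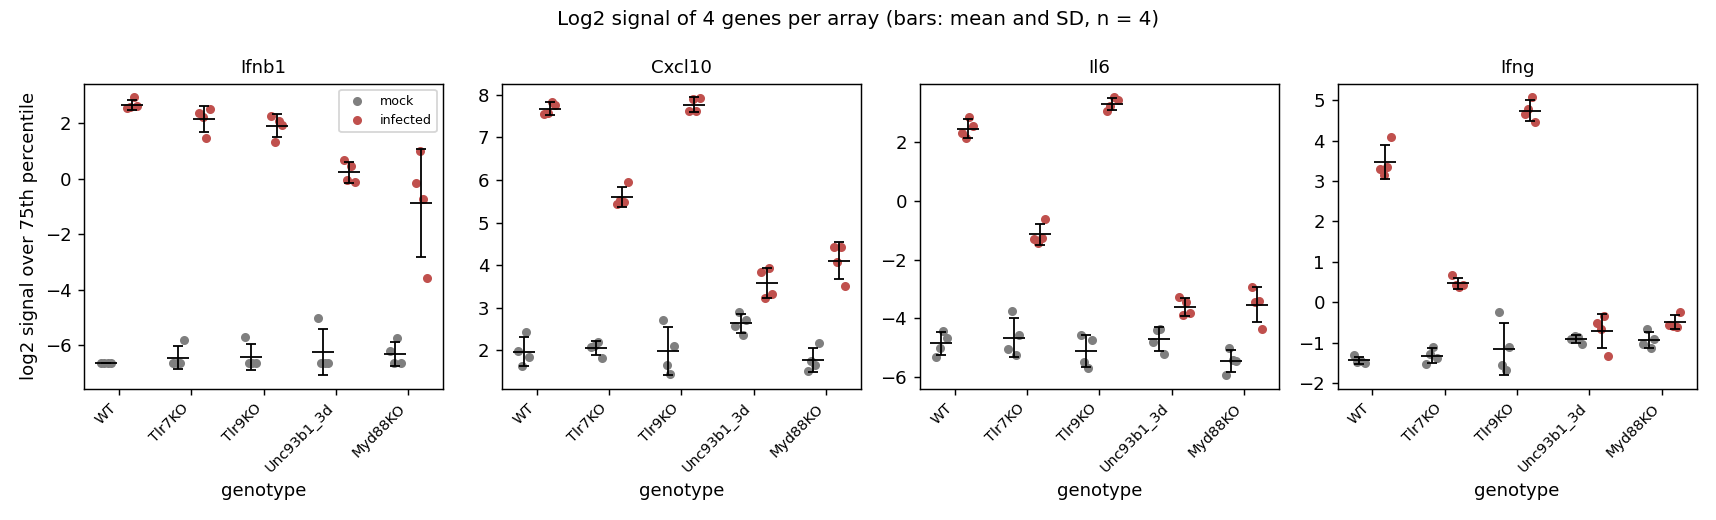
Normalised log2 signal of Ifnb1, Cxcl10, Il6 and Ifng on each array of the 5 genotypes, mock in grey and infected in red, with the mean and SD of 4 arrays; the y axis is log2 of the signal over the array's 75th percentile. Ifnb1 was at or near the floor of the scale in mock spleens and its fitted rise was 9.30 in WT and 5.44 in Myd88KO spleens, of which at least 290.3-fold and at least 20.8-fold are measured.

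The genes that respond to interferons rose as groups in WT spleens. All 34 measured type I interferon response genes rose, 34 also when adjusted over the list alone, with a median of 3.58 (3.53 with members not well above background at their bound; camera adjusted p = 1.75e-75). Among them the antiviral genes Ifit1 and Ifit3 rose by 4.86 and 4.74, Irf7, the transcription factor that amplifies interferon alpha production, by 4.28 (SE 0.30), Isg15, a ubiquitin-like modifier, by 3.86 (SE 0.40), and Usp18, which removes it, by 5.01 (SE 0.23). The per-array score of this list was 2.35 ± 0.08 (SD, n = 4) in infected and -1.25 ± 0.21 in mock spleens. The exact permutation p of 0.0286 for 4 against 4 arrays is the smallest that 70 assignments can give. Adjusted over lists and genotypes it was 0.0782, so no score passed 0.05. Of 24 measured interferon gamma response genes 23 rose, also 23 when adjusted over the list alone, with a median of 3.36 (camera adjusted p = 3.62e-46). They included the guanylate-binding protein Gbp2 (4.36), the immunity-related GTPase Iigp1 (4.12) and Cxcl9 (4.06), a chemokine for activated T cells. All 15 genes of MHC class I presentation rose, 15 also over the list alone, with a median of 1.54 (camera adjusted p = 4.47e-21), among them the peptide transporter Tap1 (2.20) and Nlrc5, the transactivator of class I genes (2.51).

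Inflammatory mediators and stress genes rose alongside in WT. Of 19 chemokines 14 rose and 1 fell (16 and 1 adjusted over the list alone; median 2.49, camera adjusted p = 6.06e-21), with Cxcl10, a chemokine for T and NK cells, up by 5.70 (SE 0.23). Of 20 inflammatory cytokines 13 rose and 1 fell (14 and 1 over the list alone; median 1.78, camera adjusted p = 6.89e-17), with Tnf at 3.94 (SE 0.19), Il1b at 2.96, the anti-inflammatory Il10 at 2.86 and Il1rn, the interleukin-1 receptor antagonist, at 4.89. Of 16 NF-kappaB targets 13 rose (13 over the list alone; median 1.20, camera adjusted p = 6.81e-10), among them Socs3 (2.69) and Rel (1.82, at least 2.67-fold). Of 15 immediate early genes 10 rose (11 rose and 1 fell over the list alone; median 1.16, camera adjusted p = 7.12e-09), led by the stress-induced factor Atf3 (4.80) and Fos (2.95). Of 10 heat shock and chaperone genes 9 rose, 9 also over the list alone (median 0.84, camera adjusted p = 1.7e-07), led by Hspa1a, the inducible Hsp70, at 5.81. The calls of these 9 groups, from interferon genes to heat shock genes, hold with an estimated correlation, at adjusted p between 3.34e-06 and 0.0128.

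**Figure D2:**
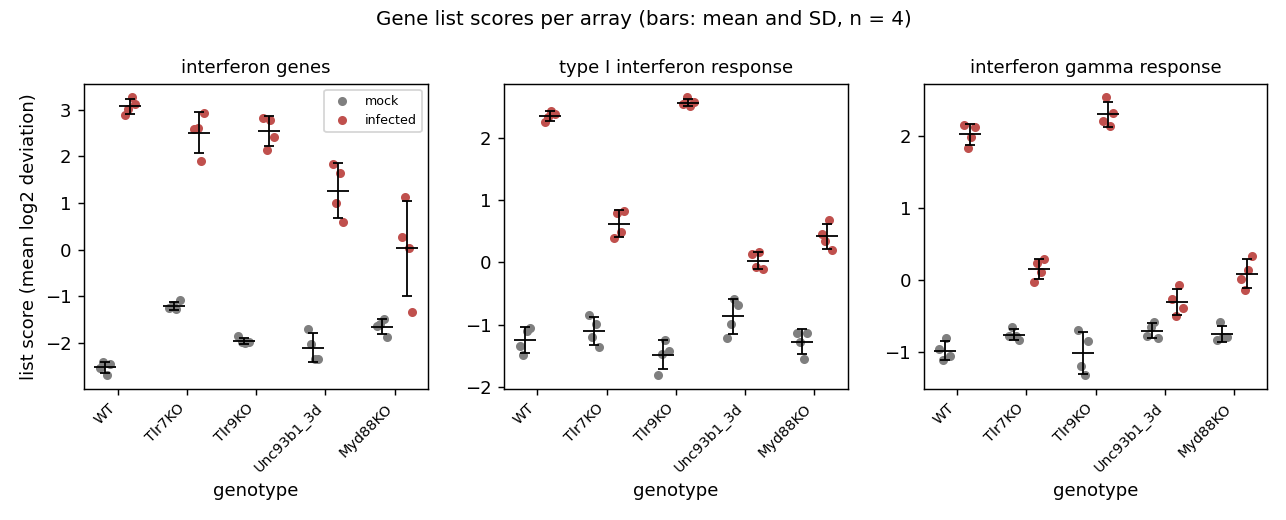
Per-array scores of the interferon genes, the type I interferon response and the interferon gamma response in the 5 genotypes; the y axis is the mean log2 deviation of the list's genes from their mean over 40 arrays, mock in grey and infected in red, with the mean and SD of 4 arrays. The type I score of infected spleens was 2.35 in WT, 2.57 in Tlr9KO, 0.62 in Tlr7KO, 0.42 in Myd88KO and 0.03 in Unc93b1 3d.

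Large falls in WT spleens were those of Kcnj16, a potassium channel (-4.91, SE 0.28, adjusted p = 1.73e-15), Ccr3, the eotaxin receptor of eosinophils (-4.00), Cd209a, a lectin of dendritic cells (-3.69), and Mrc1, the macrophage mannose receptor (-3.50). Among red pulp macrophage markers 5 of 12 fell and 0 rose (6 fell over the list alone; median -0.51), including the haemoglobin scavenger receptor Cd163 (-2.67, n = 3 infected arrays, 2 of them well above background) and the iron exporter Slc40a1 (-2.09), with camera adjusted p = 2.5e-05 but adjusted p = 0.256 with an estimated correlation. Of 14 NK and cytotoxic markers 9 rose and 2 fell (10 and 2 over the list alone; median 0.84), with Gzmb, a granzyme, at 4.83 and Klrd1, an NK receptor, at -1.06; the adjusted p of 0.00314 became adjusted p = 0.452 with an estimated correlation. Of 8 inflammatory monocyte markers 4 rose (4 rose and 1 fell over the list alone; median 1.05, adjusted p = 0.00423), including Vcan at 4.34, with adjusted p = 0.0583 with an estimated correlation. Platelet and megakaryocyte markers fell in 4 of 13 (6 over the list alone; median -0.65, adjusted p = 0.000663), with adjusted p = 0.452 with an estimated correlation.

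Other cell markers moved less in WT. Conventional dendritic cell markers rose in 1 and fell in 2 of 10, also 1 and 2 over the list alone (median -0.33, adjusted p = 0.0379, adjusted p = 0.452 with an estimated correlation), and plasmacytoid dendritic cell markers fell in 1 of 9, also 1 over the list alone (median -0.24, adjusted p = 0.258). B cell markers fell in 2 of 14, also 2 over the list alone, with Fcer2a, the low-affinity IgE receptor, at -1.84 (median -0.15, adjusted p = 0.0212, adjusted p = 0.699 with an estimated correlation). Plasma cell markers rose in 3 of 10 (3 rose and 1 fell over the list alone; median 0.25, adjusted p = 0.814). Marginal zone macrophage markers rose in 2 and fell in 1 of 6 (2 and 2 over the list alone; median 0.26, mean -0.01, adjusted p = 0.963). Stromal and endothelial markers rose in 2 and fell in 2 of 15, the same numbers over the list alone (median 0.01, mean -0.01, adjusted p = 0.693), and MHC class II genes rose in 1 and fell in 1 of 11, the same numbers over the list alone (median 0.08, adjusted p = 0.851). Toll-like receptor pathway genes rose in 6 and fell in 2 of 29 (7 and 2 over the list alone; median 0.22, adjusted p = 0.224), with Tlr7 at 1.62, Myd88 at 1.92, Tlr3 at 2.20 and Tlr11 at -1.67. Iron and haem genes rose in 3 and fell in 1 of 14 (4 and 1 over the list alone; median -0.08, mean 0.06, adjusted p = 0.823), and the haem oxygenase Hmox1 differed by 0.10 (adjusted p = 0.867). Ribosomal proteins rose in 1 of 26 and in 0 over the list alone (median 0.22, adjusted p = 0.03, adjusted p = 0.779 with an estimated correlation).

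For 6 further lists limma called 0 members in WT, over all genes or over the list alone. At unadjusted p under 0.05, 2 T cell markers of 17 were lower, and 0 members passed among neutrophil, erythroid, pancreas and adipose markers and cell cycle genes. The medians were -0.03 for T cell markers (adjusted p = 0.318), -0.67 for neutrophil markers (adjusted p = 0.0682), 0.23 for pancreas markers (adjusted p = 0.477) and 0.48 for adipose markers (adjusted p = 0.907). Erythroid markers had a median of -0.74 (adjusted p = 0.00961, adjusted p = 0.779 with an estimated correlation) and cell cycle genes of -0.53 (adjusted p = 0.0103, adjusted p = 0.779 with an estimated correlation).

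In WT mice limma called 5175 of 30542 tested genes, of which 3288 were higher and 1887 lower (63.5% higher); 2498 of them changed at least 2-fold. The median change over all tested genes was 0.12, to which single changes can be compared. The share of higher calls depended on the scaling: it was 44.9% of 5497 with normexp background correction and quantile normalisation, 44.2% of 5166 with quantile normalisation of the processed signals, and 46.2% of 3662 in the value table of the series. All 4 infected arrays lay above or below all 4 mock arrays in 24.5% of genes, where chance gives 2.86%.

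**Figure D3:**
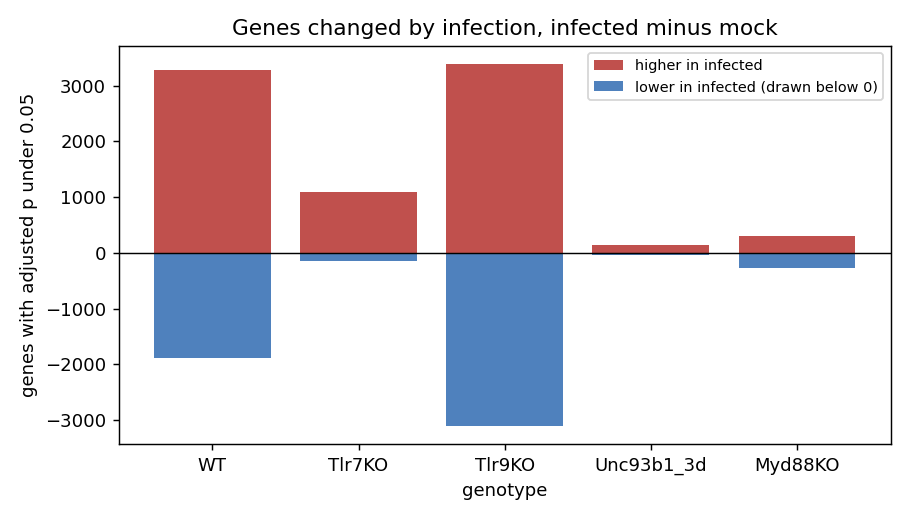
Number of genes higher (bars above 0) and lower (bars below 0) in infected than in mock spleens of each genotype, at a limma adjusted p under 0.05, n = 4 arrays per group. WT and Tlr9KO had 5175 and 6495 changed genes, Tlr7KO 1242, Myd88KO 571 and Unc93b1 3d 171.

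Tlr9KO spleens showed rises in the groups that rose in WT. Ccl7 rose by 8.84, Il6 by 8.43, Ifnb1 by 8.31 (SE 0.51, at least 148-fold, adjusted p = 7.19e-15), Ccl12 by 7.63 and Acod1 by 7.57. Without mock replicate 3 the rise of Ccl7 was 8.13. Of the Tlr9KO mock arrays Il6 was well above background on 1 of 4, and Ccl7, Ccl12 and Acod1 on 3 of 4. All 34 type I interferon response genes rose, also 34 over the list alone, with a median of 3.99 (3.97 with members at their bound; camera adjusted p = 1.59e-71). Interferon gamma response genes rose in 22 of 24 (23 over the list alone; median 3.75), interferon genes in 12 of 13 (12 over the list alone; median 4.95) and MHC class I genes in 15 of 15, also 15 over the list alone (median 1.48). Ifng rose by 5.90, Gzmb by 5.36 and Cxcl10 by 5.77. Chemokines rose in 16 and fell in 1 of 19 (17 and 1 over the list alone), cytokines rose in 14 of 20 (15 over the list alone), NF-kappaB targets in 13 of 16 (14 over the list alone) and heat shock genes in 9 of 10 (9 over the list alone), while immediate early genes rose in 10 and fell in 1 of 15 (11 and 2 over the list alone). All these calls hold with an estimated correlation.

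Falls in Tlr9KO spleens included those of Kcnj16 (-5.22, 1 of 4 infected arrays well above background), Cd209a (-4.26, or -4.92 without infected replicate 4; 2 of 4 infected arrays well above background) and Mrc1 (-3.36). Stromal and endothelial markers rose in 1 and fell in 6 of 15 (2 and 7 over the list alone; median -0.54), among them Tcf21 and Tlx1, transcription factors of spleen stroma, at -3.09 and -1.90, and Stab2, a scavenger receptor of sinusoidal endothelium, at -2.09, with adjusted p = 0.605 with an estimated correlation. Xcr1, a chemokine receptor of cross-presenting dendritic cells, fell by 2.39 and Fcer2a by 2.58. In Tlr9KO limma called 6495 genes, 3389 higher and 3106 lower (52.2% higher), and 3372 of them changed at least 2-fold. In the value table of the series 40.4% of 4802 calls were higher. The infected arrays were separated from the mock arrays in 17.5% of genes.

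In Tlr7KO spleens 5 groups rose with calls that hold with an estimated correlation, the interferon genes with the largest median among them. Ifnb1 rose by 8.57 (SE 0.51, at least 164.5-fold, adjusted p = 1.66e-13), Ifna4 by 5.69 (2 of 4 mock arrays well above background) and Ifna2 by 4.84, and 12 of 13 interferon genes rose, also 12 over the list alone (median 3.80, camera adjusted p = 1.28e-35, adjusted p = 0.000141 with an estimated correlation). Of the type I interferon response genes 30 of 34 rose (31 over the list alone; median 1.83, adjusted p = 1.71e-05 with an estimated correlation), with Ifit3 at 3.01, Ifit1 at 2.45 and Usp18 at 2.41. Ccl2 rose by 3.96, Il6 by 3.51 (2 of 4 mock arrays well above background), Cxcl10 by 3.54, Ifng by 1.79 and Acod1 by 3.16. Cxcl1, a neutrophil-attracting chemokine, rose by 4.07, Hspa1a by 4.36 and Slc2a5, the fructose transporter, by 4.44 (at least 8.12-fold).

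Interferon gamma response genes rose in 15 of 24 in Tlr7KO (19 over the list alone; median 1.16), chemokines in 10 of 19 (12 over the list alone; median 1.62, or 1.22 with members at their bound) and cytokines in 8 of 20 (13 over the list alone; median 0.92, or 0.90 with members at their bound), and these calls hold with an estimated correlation. MHC class I genes rose in 9 of 15 (13 over the list alone; median 0.57), with adjusted p = 0.0611 with an estimated correlation, and NF-kappaB targets in 3 of 16 (8 over the list alone; median 0.58), with adjusted p = 0.362 with an estimated correlation. Gzmb was called at 1.60, but not without mock replicate 1, mock replicate 2 or infected replicate 4 (adjusted p 0.0566 to 0.0718). Among the falls were Pgbd5, a transposase-derived gene (-2.11, at least 2.79-fold lower, adjusted p = 0.00447), and Ddx23, an RNA helicase of the spliceosome (-1.70, at least 2.36-fold lower).

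In Tlr7KO limma called 1242 genes, 1091 higher and 151 lower (87.8% higher), 853 of them at least 2-fold, with a median change over all genes of 0.17 and separated arrays in 13.2% of genes. The higher share was 72.4% of 2416 calls with normexp, 66.8% of 1984 with quantile normalisation, 68.3% of 884 with median centring and 58.2% of 1053 in the value table of the series. Single arrays moved the count: it was 3049 without infected replicate 2, 579 without mock replicate 1, 627 without mock replicate 2, 524 without infected replicate 1 and 494 without infected replicate 4. The detrending of the scanner software had been applied to all Tlr7KO arrays except infected replicate 1.

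In Unc93b1 3d spleens 5 groups rose with calls that hold with an estimated correlation, the interferon genes with the largest median among them. Ifnb1 rose by 6.46 (SE 0.51, at least 53.7-fold, adjusted p = 3.51e-10), Ifna2 by 4.84, Ifna5 by 4.82 and Ifna7 by 4.63, and interferon genes rose in 10 of 13 (11 rose and 1 fell over the list alone; median 4.00, camera adjusted p = 9.93e-46, adjusted p = 5.4e-05 with an estimated correlation). Of the type I interferon response genes 17 of 34 rose (27 over the list alone; median 0.82, adjusted p = 0.000244 with an estimated correlation), with Oasl1, an inhibitor of Irf7 translation, at 2.13 (adjusted p = 0.00245). Hspa1a rose by 4.26, Cxcl1 by 2.64, Ccl2 by 1.97 (adjusted p = 1.2e-06) and Cxcl2 by 2.21 (at least 2.29-fold, 3 of 4 infected arrays well above background), while Cd163 fell by 2.31 (adjusted p = 0.00653; 2 of 4 infected arrays well above background). Chemokines rose in 4 of 19 (10 rose and 1 fell over the list alone; median 0.54, adjusted p = 0.0154 with an estimated correlation) and interferon gamma response genes in 3 of 24 (9 over the list alone; median 0.42, adjusted p = 0.046 with an estimated correlation). Immediate early genes rose in 2 of 15 (8 over the list alone; median 0.71, adjusted p = 0.026 with an estimated correlation). Of the cytokines 1 of 20 rose (3 over the list alone; median 0.21, adjusted p = 0.465 with an estimated correlation), and Il6 was at 1.10 (adjusted p = 0.0931), Tnf at 0.78 (adjusted p = 0.058) and Ifng at 0.20 (adjusted p = 0.77). Red pulp macrophage markers fell in 1 of 12 (5 over the list alone; median -0.69), with adjusted p = 0.148 with an estimated correlation.

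Several genes of Unc93b1 3d spleens rested on single arrays. Cxcl10 was called at 0.95 (adjusted p = 0.0424) but not without mock replicates 1, 2 or 4 or infected replicates 1, 3 or 4 (adjusted p 0.0542 to 0.196). Ifit1 at 1.26 was lost without mock replicate 1 or 2 or any infected replicate (adjusted p 0.0624 to 0.24), Ifit3 at 1.30 without mock replicate 1 or 2 or infected replicate 1 or 3 (adjusted p 0.0578 to 0.12), and Usp18 at 1.18 without mock replicate 1 (adjusted p = 0.0716). In Unc93b1 3d limma called 171 genes, 139 higher and 32 lower (81.3% higher), 139 of them at least 2-fold, and the arrays were separated in 6.57% of genes. With median centring 92.3% of 222 calls were higher. The count was 45, 46, 1099 and 108 without mock replicates 1, 2, 3 and 4, and 78, 70, 53 and 98 without infected replicates 1, 2, 3 and 4. Same-numbered infected and mock arrays deviated together in this genotype, and with the replicate number as a block limma called 74 genes, 59 higher and 15 lower. The block ended the calls of Cd163, Ifit1, Ifit3 and Cxcl10 (adjusted p 0.0543 to 0.114). With it limma called 10 of 13 interferon genes, 9 of 34 type I and 1 of 24 gamma response genes and 0 of 15 immediate early genes. With the block and an estimated correlation the call of the interferon gamma response was lost (adjusted p = 0.0944). Those of interferon genes, the type I response, chemokines and immediate early genes were not (adjusted p 0.00184 to 0.0258).

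In Myd88KO spleens 4 groups rose with calls that hold with an estimated correlation, the interferon genes and the interferon and chemokine responses. Ifnb1 rose by 5.44 (SE 0.51, at least 20.8-fold, adjusted p = 2.56e-08) and Ifna4 by 2.98 (SE 0.44, adjusted p = 4.91e-05; 1 of 4 mock arrays well above background), and interferon genes rose in 7 of 13 (9 rose and 1 fell over the list alone; median 1.95, adjusted p = 0.0283 with an estimated correlation). Type I interferon response genes rose in 30 of 34 (31 over the list alone; median 1.70, or 1.68 with members at their bound; camera adjusted p = 4.65e-89, adjusted p = 6.64e-07 with an estimated correlation), with Ifit3 at 2.82, Ifi44 at 2.61 and Irf7 at 1.67. Interferon gamma response genes rose in 11 of 24 (14 over the list alone; median 0.78, adjusted p = 0.000685 with an estimated correlation), with Socs1, a suppressor of cytokine signalling, at 1.48, and chemokines in 7 of 19 (9 rose and 1 fell over the list alone; median 0.65, or 0.35 with members at their bound, adjusted p = 0.0386 with an estimated correlation). Cytokines rose in 1 of 20 (2 over the list alone; median 0.04, adjusted p = 0.0595), Il6 rose by 1.92 (1 of 4 mock arrays well above background), and Tnf was at 0.42 (adjusted p = 0.345), Il1b at 0.78 (adjusted p = 0.105) and Ifng at 0.44 (adjusted p = 0.407).

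Infected replicate 4 of Myd88KO had the lowest values of its group in Ifnb1 and Ifna4. Ifnb1 lay at -3.57 on it, against -0.73 to 0.99 on the other infected arrays, and Ifna4 at -3.87, against -1.91 to -0.57. The score of the interferon genes on it was -1.33, against 0.05 to 1.13. Without that array the rise of Ifnb1 was 6.34 and that of Ifna4 3.59, and without infected replicate 2 that of Ifnb1 was 4.82. Hspa1a rose by 2.28, and by 3.1 without infected replicate 4, where it lay at -2.33, against -2.15 as the mean of the mock arrays.

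MHC class I genes rose in 3 of 15 in Myd88KO (10 over the list alone; median 0.47, adjusted p = 0.051 with an estimated correlation), and limma called 0 of 16 NF-kappaB targets, with 5 at unadjusted p under 0.05, all higher. Of erythroid markers limma called 0 of 23 over all genes, 7 lower over the list alone and 12 at unadjusted p under 0.05, all lower; the median was -1.42, with adjusted p = 0.325 with an estimated correlation. Isg15 was called at 1.49 but not without mock replicate 2 or 3 or any infected replicate (adjusted p 0.0681 to 0.184). In Myd88KO limma called 571 genes, 305 higher and 266 lower (53.4% higher), 393 of them at least 2-fold, and the arrays were separated in 12.6% of genes. The higher share was 70.7% of 471 calls with normexp, 70.8% of 552 with quantile normalisation, 82.9% of 680 with median centring, 85.4% of 280 in the value table of the series and 66.4% of 676 with the array's signal distribution as a covariate. The count was 290 without mock replicate 1, 307 without mock replicate 4 and 276 without infected replicate 3. In this genotype every mock array and 0 infected arrays had been detrended by the scanner software.

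Whether the response depends on a sensor was tested as the difference of the infection response between genotypes, in which a constant difference between slides cancels. Detrending of Myd88KO mock but not infected arrays does not cancel and can enter Myd88KO differences. Ifnb1 and Cxcl2 were well above background on 0 mock arrays of any genotype, and Ifna4 on 0 of 4 WT mock arrays, so differences of their responses are fitted values that depend on the floor. Those of Ccl7, Acod1, Il6, Kcnj16 and Cd209a also rest in part on groups in which, as given above, only some arrays were well above background. Against WT, the Tlr7KO response was smaller for inflammatory mediators. The difference was -4.64 for Ccl7, -4.63 for Acod1, -3.80 for Il6 (adjusted p = 4.88e-07), -3.68 for Il1rn (-3.10 without Tlr7KO infected replicate 1), -3.41 for Ccl2 (adjusted p = 4.56e-08) and -3.12 for Ifng (adjusted p = 1.43e-07). It was 3.76 for Kcnj16 and 3.48 for Cd209a. Both fell in WT. Type I interferon response genes were lower in 30 of 34 (33 over the list alone; median -1.84, adjusted p = 1.02e-05 with an estimated correlation), with Irf7 at -2.29 and Usp18 at -2.60, and interferon gamma response genes in 21 of 24 (22 over the list alone; median -2.20), with Gbp2 at -3.09. Cytokines were lower in 10 of 20 (13 over the list alone; median -1.19) and MHC class I genes in 9 of 15 (12 over the list alone; median -0.97), and both calls hold with an estimated correlation.

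Interferon genes in the same test were lower in 7 of 13 (10 over the list alone; median -1.89, adjusted p = 0.0187 with an estimated correlation), with Ifna7 at -2.80. More of this difference lay between the mock than between the infected arrays: the score of the interferon genes was -1.20 in Tlr7KO and -2.52 in WT mock spleens, and 2.51 and 3.07 in infected spleens. The mock arrays lie on different slides, and on the Tlr7KO slide 7377 genes were higher than in WT mock spleens. Ifnb1 differed by -0.72 (adjusted p = 0.776), Ifna4 by -1.59 (adjusted p = 0.176) and Isg15 by -1.81 (adjusted p = 0.0631), so a difference was not detected for these genes. In all limma called 1287 genes, 485 with a higher and 802 with a lower response in Tlr7KO (37.7% higher), with a median over all genes of 0.06. With median centring 24.8% of 1092 calls were higher. No left-out array moved the count by over 1.5 times.

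In the main fit Tlr9KO and WT responses differed in few called genes. The response of Il33, an alarmin cytokine, was higher by 1.53 in Tlr9KO (adjusted p = 0.0109), and that of the chemokine Cxcl2 by 1.40 (adjusted p = 0.0152), although Cxcl2 was at -0.17 in the value table of the series. Ddit4, a stress-induced inhibitor of mTORC1, was called at 2.05 but lost without WT mock replicates 1 to 3, any WT infected replicate, Tlr9KO mock replicates 1 to 3 or Tlr9KO infected replicate 1 (adjusted p 0.0613 to 0.122). Ifnb1 differed by -0.99 (adjusted p = 0.878), Ifng by 0.99 (adjusted p = 0.436), Cxcl10 by 0.07 (adjusted p = 0.976) and Il6 by 1.12 (adjusted p = 0.7). The type I interferon list had a median difference of 0.39, with camera adjusted p = 3.17e-11 but adjusted p = 0.378 with an estimated correlation, and the interferon genes a median of -1.33 (1 higher and 6 lower over the list alone), with adjusted p = 0.404 with an estimated correlation.

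For Tlr9KO against WT limma called 6 genes, 5 higher and 1 lower (83.3% higher), and 1709 at unadjusted p under 0.05. With quantile normalisation 2 genes were called, both higher, and with the covariate 6, all higher. Quantile normalisation ended the calls of Il33 (adjusted p = 0.0666) and Cxcl2 (adjusted p = 0.0813). With only the arrays compared limma called 0 genes, with 1125 at unadjusted p under 0.05. The count was 3 without WT mock replicate 1, 2 or 3 or Tlr9KO mock replicate 2 or 3, 19 without Tlr9KO mock replicate 4, and 13, 16 and 50 without Tlr9KO infected replicates 2, 3 and 4. A low count does not show that the responses were alike.

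The Unc93b1 3d response was smaller than that of WT for interferon response genes and inflammatory mediators. The difference was -6.82 for Ccl7, -6.59 for Acod1, -6.22 for Il6 (adjusted p = 4.58e-12), -5.39 for Ccl2 (adjusted p = 2.92e-13), -5.09 for Gzmb, -4.75 for Cxcl10 and -4.70 for Ifng (both adjusted p = 2.72e-12). Ifnb1 was lower by -2.83 (adjusted p = 0.0101). Kcnj16 was higher by 3.80, Cd209a by 3.52 and Adam22, a neuronal adhesion protein, by 3.43. Responses were lower in 32 of 34 type I interferon response genes (33 over the list alone; median -2.75), interferon gamma response genes in 20 of 24 (23 over the list alone; median -2.71), cytokines in 13 of 20 (14 over the list alone; median -1.75), chemokines in 10 of 19 (14 over the list alone; median -1.91) and MHC class I genes in 13 of 15 (14 over the list alone; median -1.16), and these calls hold with an estimated correlation. With the replicate number as a block that of MHC class I genes was lost (adjusted p = 0.0542). Interferon genes were lower in 10 of 13 (12 over the list alone; median -2.28), with adjusted p = 0.0749 with an estimated correlation. Limma called 2398 genes, 671 higher and 1727 lower (28.0% higher), with a median over all genes of -0.21. Higher calls made up 48.8% of 2539 with normexp, 50.1% of 2278 with quantile normalisation, 45.5% of 1993 with median centring and 45.1% of 1780 in the value table of the series.

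The Myd88KO response was smaller than that of WT for the same kinds of mediators and for the interferon genes themselves. The difference was -5.92 for Ccl7, -5.91 for Acod1, -5.40 for Il6 (adjusted p = 3e-10), -5.31 for Ccl2 (adjusted p = 4.47e-13) and -4.47 for Ifng. Interferon genes were lower in 13 of 13, also 13 over the list alone (median -4.19, adjusted p = 0.000349 with an estimated correlation), with Ifna7 at -4.98, Ifna4 at -4.30 (adjusted p = 1.49e-05) and Ifnb1 at -3.86 (adjusted p = 0.000635). Without Myd88KO infected replicate 4 these were -3.69 for Ifna4 and -2.95 for Ifnb1, and without infected replicate 2 Ifnb1 was at -4.47. Type I interferon response genes were lower in 30 of 34 (33 over the list alone; median -1.92), interferon gamma response genes in 20 of 24 (22 over the list alone; median -2.12), cytokines in 13 of 20 (15 over the list alone; median -2.08) and chemokines in 10 of 19 (14 over the list alone; median -1.96), and these calls hold with an estimated correlation. Kcnj16 and Adam22 were higher by 3.42 and 2.97. Limma called 1498 genes, 426 higher and 1072 lower (28.4% higher), with a median over all genes of -0.15. Higher calls made up 44.8% of 1440 with normexp, 47.8% of 1290 with quantile normalisation, 55.4% of 1433 with median centring and 48.8% of 1019 in the value table of the series.

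The Tlr7KO response was also set directly against the Tlr9KO response. It was lower for Ccl7 (-5.17, or -4.47 without Tlr9KO mock replicate 3), Il6 (-4.92, adjusted p = 1.49e-09), Ifng (-4.11, adjusted p = 3.07e-10) and Cxcl10 (-2.23), and higher for Kcnj16 (4.07) and Cd209a (4.05, or 4.71 without Tlr9KO infected replicate 4). Ifnb1 differed by 0.26 (adjusted p = 0.873) and Ifna4 by -0.07 (adjusted p = 0.963). Type I interferon response genes were lower in 32 of 34 (33 over the list alone; median -2.13) and interferon gamma response genes in 22 of 24 (22 over the list alone; median -2.50), while interferon genes were lower in 1 of 13 (1 over the list alone; median -0.63, adjusted p = 0.547 with an estimated correlation). Limma called 3070 genes, 1762 higher and 1308 lower (57.4% higher), with a median over all genes of 0.12; with median centring 36.6% of 2667 calls were higher.

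Unc93b1 3d and Tlr7KO responses differed in 41 called genes. The response was lower in Unc93b1 3d for Cxcl10 (-2.60, adjusted p = 6.61e-05), Il6 (-2.42, adjusted p = 0.00856), Ccl2 (-1.98, adjusted p = 0.00451), Ccl3, a macrophage chemokine (-1.74), and Ifi204, an interferon-inducible DNA-binding protein (-1.38). Ifnb1 differed by -2.11 (adjusted p = 0.148). Responses were lower in 4 of 34 type I interferon response genes (20 over the list alone; median -0.92) and 4 of 19 chemokines (10 over the list alone; median -1.28), each with adjusted p = 0.208 with an estimated correlation. Limma called 41 genes, 1 higher and 40 lower (2.44% higher), with a median over all genes of -0.23. With the replicate number as a block it called 133, and with array weights 7019. Higher calls made up 14.3% of 105 with normexp, 24.2% of 120 with quantile normalisation and 13.5% of 52 in the value table of the series. Without Tlr7KO mock replicates 1, 2 and 4 the count was 17, 12 and 73, and without Tlr7KO infected replicates 1 to 4 it was 26, 1094, 27 and 10. Without Unc93b1 3d mock replicates 1, 2 and 3 it was 27, 13 and 292, and without infected replicates 1, 2 and 4 it was 76, 13 and 13.

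Myd88KO and Tlr7KO responses differed in 7 called genes, among them the chemokines Cxcl5 (-2.67), Cxcl1 (-2.63), Ccl2 (-1.91) and Cxcl2 (-1.38), all lower in Myd88KO. Each of these calls rested on single arrays. Ccl2 was lost without Tlr7KO infected replicate 4 (adjusted p = 0.0629), Cxcl1 and Cxcl2 without Tlr7KO infected replicate 1 or 4 or Myd88KO infected replicate 3 (adjusted p 0.0547 to 0.0629), and Cxcl5 without Tlr7KO infected replicate 4, Myd88KO mock replicate 4 or Myd88KO infected replicate 3 (adjusted p 0.0547 to 0.0938). Cxcl2 was well above background on 0 Myd88KO infected arrays, and was at 0.17 in the value table of the series. Interferon genes had a median difference of -2.20 (11 lower over the list alone), with adjusted p = 0.0509 with an estimated correlation, and Ifnb1 differed by -3.13 and Ifna4 by -2.71 (both adjusted p = 0.0822), or by -2.23 and -2.10 without Myd88KO infected replicate 4. The type I interferon list had a median of -0.07 and a mean of -0.03, while the test pointed up (camera adjusted p = 0.493, adjusted p = 0.997 with an estimated correlation). Of the 7 genes 1 was higher and 6 lower (14.3% higher), 4273 passed at unadjusted p under 0.05, and the median over all genes was -0.18. The higher share was 29.6% of 44 with quantile normalisation and 32.4% of 37 in the value table of the series, and with median centring limma called 0 genes, with 4843 at unadjusted p under 0.05. The count was 84 without Tlr7KO mock replicate 4, 3 and 544 without Tlr7KO infected replicates 1 and 2, and 20, 14 and 2 without Myd88KO infected replicates 1, 2 and 3. Without Tlr7KO infected replicate 4 limma called 0 genes, with 3138 at unadjusted p under 0.05, and with only the arrays compared also 0, with 5544.

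Responses of different genotypes share no arrays and were compared across genes, which are not independent replicates. In WT and Tlr9KO 2266 genes rose in both, against 364.8 for independent lists, and 1557 fell in both, against 191.9; the log2 changes correlated with Pearson r = 0.773 and Spearman rho = 0.622. WT shared 560 rises and 58 falls with Tlr7KO (117.5 and 9.33 for independent lists; r = 0.517, rho = 0.515). It shared 288 and 58 with Myd88KO (32.8 and 16.4; r = 0.333, rho = 0.279) and 94 and 15 with Unc93b1 3d (15.0 and 1.98; r = 0.111, rho = 0.0044). Over the 3389 genes raised in Tlr9KO the median change was 0.86 in WT, 0.37 in Tlr7KO, 0.26 in Myd88KO and 0.11 in Unc93b1 3d. Less the median over all genes it was 0.74, 0.19, 0.25 and 0.18, so the order of these 3 mutants depends on the scaling. Over the 3106 genes lowered in Tlr9KO it was -0.62, -0.07, -0.13 and -0.16 in the same order, and -0.74, -0.25, -0.13 and -0.09 less the median over all genes. A set of 65 genes rose in all 5 genotypes, where independent lists give 0.000592.

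Mock groups were compared to describe the baseline of each genotype, and since each genotype lies on a slide of its own these differences, that of Tlr7 aside, cannot be told apart from slide. Tlr7KO mock spleens were lower than WT mock spleens in Tlr7 (-6.79) and in Igf2bp3, an RNA-binding protein (-1.78), and higher in the vomeronasal receptor Vmn1r56 (3.63, at least 10.03-fold) and the thioredoxin Txndc8 (3.33). Interferon genes were higher in 9 of 13, also 9 over the list alone (median 1.37, camera adjusted p = 0.00312), with adjusted p = 0.767 with an estimated correlation. Limma called 7948 genes, 7377 higher and 571 lower (92.8% higher), with a median over all genes of 0.14. The higher share was 54.3% of 3960 with normexp, 52.5% of 4124 with quantile normalisation, 31.7% of 14644 with median centring, 67.4% of 1146 in the value table of the series and 74.5% of 271 with the covariate. All Tlr7KO mock arrays had been detrended by the scanner software and 0 WT arrays had.

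Tlr9KO mock spleens were higher than WT mock spleens in Mst1r, the receptor of macrophage-stimulating protein (3.81, SE 0.44, adjusted p = 3.88e-07) and the cyclin Ccne2 (3.34, at least 7.54-fold), and lower in the hyaluronidase Hyal3 (-2.20, at least 2.79-fold). Mst1r and Hyal3 lie near Tlr9. Of genes within 10 Mb of Tlr9, 33 of 225 were called (14.7%), against 1270 of 17093 elsewhere (7.43%; two-sided Fisher's exact test p = 0.000192, adjusted p = 0.000768 over the 4 targets). The same share was 6 of 53 near Tlr7 (11.3% against 17.8% elsewhere, adjusted p = 0.56), 8 of 295 near Unc93b1 and 18 of 142 near Myd88 (adjusted p = 0.629 for both). In the type I interferon response 3 of 34 genes were lower (4 over the list alone; median -0.22), with adjusted p = 0.75 with an estimated correlation. Limma called 2944 genes, 2151 higher and 793 lower (73.1% higher), and 61.6% of 1546 were higher in the value table of the series. The count was 1385 and 1509 without WT mock replicates 1 and 2, and 1853 and 5632 without Tlr9KO mock replicates 1 and 4.

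Unc93b1 3d mock spleens were lower than WT mock spleens in Tmem245, a membrane protein (-4.52, SE 0.16, adjusted p = 2.99e-20), and higher in the stefins Cstdc4 (2.82) and Stfa2l1 (2.54), which inhibit cysteine proteases. Without Unc93b1 3d mock replicate 4 Cstdc4 was at 2.12 and Stfa2l1 at 1.83. In the type I interferon response 5 of 34 genes were higher (9 over the list alone; median 0.46, camera adjusted p = 4.88e-05), with adjusted p = 0.819 with an estimated correlation. Limma called 1576 genes, 778 higher and 798 lower (49.4% higher). The count was 574, 573 and 898 without WT mock replicates 1, 2 and 3, and 595, 576, 3680 and 839 without Unc93b1 3d mock replicates 1 to 4.

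Myd88KO mock spleens were lower than WT mock spleens in Epx, the eosinophil peroxidase (-3.82, or -4.56 without WT mock replicate 3; 1 of 4 Myd88KO mock arrays well above background), Ear6, an eosinophil ribonuclease (-3.29), Prg2, the eosinophil major basic protein (-3.11), and Xcr1 (-2.86), which lies near Myd88. Red pulp macrophage markers were lower in 7 of 12 (8 over the list alone; median -0.79, camera adjusted p = 9.25e-12), including the complement component C1qa (-1.49, n = 3 Myd88KO mock arrays) and Cd163 (-1.91), with adjusted p = 0.127 with an estimated correlation. Iron and haem genes were lower in 4 of 14 (4 over the list alone; median -0.38), also with adjusted p = 0.127 with an estimated correlation. Interferon genes were higher in 4 of 13 (6 over the list alone; median 0.79), with adjusted p = 0.765 with an estimated correlation. Limma called 4406 genes, 3808 higher and 598 lower (86.4% higher), with a median over all genes of 0.21. The higher share was 64.7% of 2581 with normexp, 65.4% of 2554 with quantile normalisation, 62.4% of 3229 with median centring and 60.9% of 1198 in the value table of the series. The count was 2574 without Myd88KO mock replicate 3, and all Myd88KO mock arrays had been detrended by the scanner software.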

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

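Chosen only after the result was seen were the tests of regrouped arrays for infection in Unc93b1 3d, the 7 tests of regrouped arrays with each genotype's mean removed, the 4 that keep the pairs of Unc93b1 3d, and the tests of loss of Tlr7, of signal shared between interferon paralogs and of a different response in WT infected replicate 1.

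The difference of the infection response itself was tested between genotypes, and it was past the threshold for 1287 genes between Tlr7KO and WT, 6 between Tlr9KO and WT, 2398 between Unc93b1 3d and WT, and 1498 between Myd88KO and WT. It was past it for 3070 genes between Tlr7KO and Tlr9KO, 41 between Unc93b1 3d and Tlr7KO, and 7 between Myd88KO and Tlr7KO. For each, the genotype labels of the arrays were regrouped 100 times, the real grouping included, within infected and within mock arrays. As many genes or more came from 10 groupings for Tlr7KO and WT (highest other 11619), 13 for Tlr9KO and WT (1507), 2 for Unc93b1 3d and WT (2712), 5 for Myd88KO and WT (7179), 11 for Tlr7KO and Tlr9KO (14961), 10 for Unc93b1 3d and Tlr7KO (12590) and 12 for Myd88KO and Tlr7KO (10091). By this count chance is excluded for Unc93b1 3d and WT and for no other pair. The highest other groupings exchange more mock than infected arrays between slides, or, for Myd88KO and WT, more infected than mock. Either turns a constant difference between slides into a difference of responses. With genotype means removed, 1 grouping of 100 reached the real count for Tlr7KO (highest other 559), Unc93b1 3d (1385) and Myd88KO (358) against WT. The number was also 1 for Tlr7KO and Tlr9KO (1442) and 2 for Unc93b1 3d and Tlr7KO (395). It was 3 for Myd88KO and Tlr7KO (108) and 5 for Tlr9KO and WT (899). Also uncorrected, this excludes chance for all but the last, but all Myd88KO and Tlr7KO calls were lost with median centring. These groupings part same-numbered Unc93b1 3d arrays, which the real one does not. Among 100 groupings that keep these pairs, and so exchange as many infected as mock arrays, only the real one reached its count, with or without each genotype's mean removed. The highest other was 1 for Unc93b1 3d and WT in both forms, and 1 and, with the mean removed, 38 for Unc93b1 3d and Tlr7KO. This excludes chance for both only if the pairing, read from the same data, holds.

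For infected against mock arrays all 35 splits of the 8 arrays were run. The real count was the highest in WT (1 of 35 splits; 5175 genes, highest other 13) and Tlr9KO (1 of 35; 6495, highest other 4535), which excludes chance. In Tlr7KO 2 of 35 splits gave as many genes (1242, highest other 1562, which exchanged mock replicate 4 and infected replicate 2), in Unc93b1 3d 2 of 35 (171, highest other 482) and in Myd88KO 3 of 35 (571, highest other 1440), so for these 3 counts chance is not excluded. In Unc93b1 3d, where same-numbered arrays deviated together, the real split parts all 4 pairs; of the 8 splits that do, which are too few for a share under 0.05, the highest other called 0 genes (limma; at most 2628 at unadjusted p under 0.05), and the split with 482 genes parts 2 pairs. With the replicate block the count was 74. For mutant mock against WT mock the real split was the highest in every case, 1 of 35, with 7948 genes in Tlr7KO (highest other 544), 2944 in Tlr9KO (1315), 1576 in Unc93b1 3d (12) and 4406 in Myd88KO (5). Also uncorrected, this excludes chance but not slide.

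Interferon genes rose in all 5 genotypes, also in Unc93b1 3d and Myd88KO, where 1 of 20 inflammatory cytokines was called in each. Since infected and mock arrays lay in different slide rows, a row effect on dim spots was tested. In each mutant the median change of the interferon genes was at percentile 100 of 10000 random lists of the same mean level. It was 3.80 in Tlr7KO (upper percentile limit of random lists 0.31) and 1.95 in Myd88KO (0.16). Genes of such lists need not be as dim in mock spleens, so this cannot decide on a row effect. Signal shared between interferon alpha copies is argued against as the whole cause, since Ifnb1, which is no such copy, passed the test in every genotype, with its lowest fitted change, 5.44, and its lowest bound, at least 20.8-fold, both in Myd88KO. A row effect on dim spots stays open, and what the induction needs in each genotype was not tested.

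Far more genes were higher than lower in Tlr7KO mock against WT mock, 7377 against 571. Of the higher calls 89.2% lay among the dimmer genes, ranked at the median on the arrays of the other 8 groups, which is what a different signal distribution of the Tlr7KO slide would give. The split also moved with the scaling, to 52.5% higher with quantile normalisation and to 271 genes in all with the covariate. Loss of Tlr7 could be separated from the slide only on slides that hold both genotypes, and 0 do, so these cannot be told apart.

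WT infected replicate 1 had a negative-control median of 48, above the 21 to 22 of the WT mock arrays, in control spots that no comparison uses. On it the dimmest genes lay a median 1.26 log2 units above the other WT infected arrays, against 0.15 over all genes. After background subtraction its controls lay at -0.0078 of the 75th percentile, below the rest, so background is not shown as the cause. A different response of that mouse stays open: its type I interferon score was 2.25 (others 2.34 to 2.43).

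The inflammatory cytokine score of Myd88KO mock replicate 2 was -0.49, apart from the other replicates of its group. The chemokine score of WT infected replicate 2 was 1.68, also apart from the others of its group. Of 70 groups of scores examined these 2 stood apart, where chance gives 3.5.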

How the results depend on the processing

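Of the tests here, normexp on median signals, both floors, the covariate and the removal of 4 arrays in doubt were chosen only after results had been seen. The shift of the type I interferon list kept its direction and its side of the threshold in every infection contrast under each alternative run, and its scores did not pass the threshold in any genotype or alternative for which they were computed. With an array left out the shift ran from 3.51 to 3.68 in WT, 1.73 to 1.91 in Tlr7KO, 3.74 to 4.05 in Tlr9KO, 0.73 to 0.92 in Unc93b1 3d and 1.55 to 1.78 in Myd88KO, and against WT from -1.97 to -1.70 in Tlr7KO, 0.30 to 0.53 in Tlr9KO, -2.92 to -2.65 in Unc93b1 3d and -2.04 to -1.81 in Myd88KO. The shift of Tlr9KO against WT, 0.39, lost its call with an estimated correlation (adjusted p = 0.378). Counts of changed genes moved far more. Of 800 named calls 715 stayed past the threshold with normexp, 710 with quantile normalisation, 683 with median centring, 696 with the covariate, 763 with the replicate block and 618 with only the arrays compared; of 8920 calls with an array left out 7907 did. Reversed were Igtp in Tlr7KO mock (-0.0685 with median centring), whose call was also lost without WT mock replicate 1, 2 or 4 or Tlr7KO mock replicate 1, 3 or 4 (adjusted p 0.0516 to 0.126), Egr3 there (-0.0663 with the covariate), lost without WT mock replicate 3 or 4 (adjusted p 0.0539 to 0.075), and, in the value table of the series, Atf3 for Tlr7KO against WT (0.0292), and Cxcl2 for Tlr9KO against WT (-0.17) and for Myd88KO against Tlr7KO (0.17), where its call was lost without Tlr7KO infected replicate 1 or 4 or Myd88KO infected replicate 3 (adjusted p 0.0547 to 0.0629). The cause was not tested for these or for the counts below, except where fewer arrays or a stricter threshold enter by construction. The share of probes well above background, 53.6% at the lowest, limits what dim genes can show.

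Counts that moved by over 1.5 times are given for infection in a genotype (its name alone), for differences of responses (joined by "against") and for mock groups against WT mock. With normexp they were 2416 in Tlr7KO, 15 for Tlr9KO against WT, 105 for Unc93b1 3d against Tlr7KO, 41 for Myd88KO against Tlr7KO, 3960 in Tlr7KO mock and 2581 in Myd88KO mock. With quantile normalisation the same counts were 1984, 2, 120, 44, 4124 and 2554. With median centring they were 1 for Unc93b1 3d against Tlr7KO, 0 for Myd88KO against Tlr7KO (limma; 4843 at unadjusted p under 0.05) and 14644 in Tlr7KO mock. In the value table of the series they were 280 in Myd88KO, 1 for Tlr9KO against WT, 37 for Myd88KO against Tlr7KO, and 1146, 1546, 730 and 1198 in Tlr7KO, Tlr9KO, Unc93b1 3d and Myd88KO mock. With no filter they were 1874 in Tlr7KO, 89 for Unc93b1 3d against Tlr7KO and 100 for Myd88KO against Tlr7KO, and with probes well above background on all 40 arrays 16 for Tlr9KO against WT, 2389 in Tlr7KO mock and 2108 in Myd88KO mock. With all probes the count for Myd88KO against Tlr7KO was 25, and with a trended and robust spread 4. With only the arrays compared they were 598 in Tlr7KO, 2641 in Tlr9KO, 36 in Unc93b1 3d, 187 in Myd88KO, 1468 for Tlr7KO against Tlr9KO, 19 for Unc93b1 3d against Tlr7KO, 466 in Tlr9KO mock and 7220 in Myd88KO mock, and 0 for Tlr9KO against WT and Myd88KO against Tlr7KO (limma; 1125 and 5544 at unadjusted p under 0.05).

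With array weights they were 11271 in WT, 5987 in Tlr7KO, 4770 in Unc93b1 3d and 3723 in Myd88KO. Against WT they were then 6586 for Tlr7KO, 1987 for Tlr9KO, 9192 for Unc93b1 3d and 6412 for Myd88KO, and 6646 for Tlr7KO against Tlr9KO, 7019 for Unc93b1 3d against Tlr7KO and 2139 for Myd88KO against Tlr7KO. In mock groups they were 13173, 16961, 10792 and 14014 in Tlr7KO, Tlr9KO, Unc93b1 3d and Myd88KO. At an adjusted p under 0.01 they were 3351 in WT, 486 in Tlr7KO, 46 in Unc93b1 3d and 230 in Myd88KO, 642, 1253 and 752 for Tlr7KO, Unc93b1 3d and Myd88KO against WT, 1584 for Tlr7KO against Tlr9KO, 10 for Unc93b1 3d against Tlr7KO, and 5018, 976, 372 and 1889 in the mock groups in the order above. They were 0 for Tlr9KO against WT and Myd88KO against Tlr7KO (limma; 1709 and 4273 at unadjusted p under 0.05). With at least a 2-fold change they were 2498 in WT, 3372 in Tlr9KO, and 1366, 955 and 2867 in Tlr9KO, Unc93b1 3d and Myd88KO mock. With a floor of 0.02 they were 2062 in Tlr7KO, 14 for Tlr9KO against WT, 115 for Unc93b1 3d against Tlr7KO and 200 for Myd88KO against Tlr7KO. With the covariate they were 665 in Tlr7KO, 24 for Unc93b1 3d against Tlr7KO, 1 for Myd88KO against Tlr7KO, and 271, 2382 and 1304 in Tlr7KO, Unc93b1 3d and Myd88KO mock. Without the 4 arrays in doubt (WT infected replicate 1, Tlr9KO mock replicate 1, Myd88KO infected replicates 2 and 3) they were 2444 in Tlr7KO, 999 in Unc93b1 3d, 280 in Myd88KO, 385 for Unc93b1 3d against Tlr7KO, 18 for Myd88KO against Tlr7KO and 4005 in Unc93b1 3d mock.

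With an array left out the counts ran from 4155 to 4942 in WT, 494 to 3049 in Tlr7KO, 5275 to 6955 in Tlr9KO, 45 to 1099 in Unc93b1 3d and 276 to 817 in Myd88KO. Against WT they ran from 949 to 1548 for Tlr7KO, 3 to 50 for Tlr9KO, 1728 to 3428 for Unc93b1 3d and 1164 to 1721 for Myd88KO. They ran from 2313 to 3713 for Tlr7KO against Tlr9KO, 10 to 1094 for Unc93b1 3d against Tlr7KO and 0 to 544 for Myd88KO against Tlr7KO (limma; the 0 came with 3138 at unadjusted p under 0.05). In mock groups they ran from 6464 to 7559 in Tlr7KO, 1385 to 5632 in Tlr9KO, 573 to 3680 in Unc93b1 3d and 2574 to 4969 in Myd88KO. In WT, Tlr7KO, Tlr9KO and Myd88KO the deviations of same-numbered arrays correlated across genes at -0.43 to 0.57. This was over 0.1 in 5 of 16 pairs, and 5 of 16 arrays correlated best with their own number. In Unc93b1 3d the numbers were taken, from the same data, to pair the arrays, and the block ended 11 of 29 named calls there. For genes printed for Unc93b1 3d it changed no call other than those stated with them. With the block the counts were 74 in Unc93b1 3d, 133 for Unc93b1 3d against Tlr7KO, 36 for Myd88KO against Tlr7KO and 0 for Tlr9KO against WT (limma; 2038 at unadjusted p under 0.05). A slide block leaves infection contrasts as they are and mock contrasts could not be fitted with it. Not run were normexp on mean signals, which the files used here lack, and the type I list without members of other lists, since there are 0 such members.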

Other observations

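Of the 65 genes that rose in all 5 genotypes 54 have a current symbol, and 3 of them are described here, with no test of what they share. Casr, the calcium-sensing receptor, rose at least 7.78-fold in WT, 4.88-fold in Tlr9KO, 10.73-fold in Unc93b1 3d and 5.88-fold in Myd88KO, and by 3.53 on the log2 scale in Tlr7KO, where 1 of 4 mock arrays was well above background. In Myd88KO its rise rests on 3 of 4 infected arrays, at -2.00 to -1.16, while infected replicate 4 lay at -5.74 and was not well above background; the fitted change of 3.95 was 4.97 without it. Gdf15, a stress-induced cytokine of the transforming growth factor beta family, rose by 3.13, 3.33, 2.40, 2.89 and 2.95 in WT, Tlr7KO, Tlr9KO, Unc93b1 3d and Myd88KO (SE 0.35, adjusted p between 2e-08 and 3.84e-06). Hspa1a rose in the same order by 5.81, 4.36, 5.48, 4.26 and 2.28. In Myd88KO it lay at 0.51 to 1.46 on the infected arrays other than replicate 4, described above. With limma, 0 genes fell in all 5.

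Pancreas markers varied between arrays of every group. Their score over 19 genes ran from -4.40 to 7.60 over the 40 arrays and lay above 0 on 15, 8 of 20 mock and 7 of 20 infected arrays. In WT the exact permutation p of infected against mock scores was 0.857. The erythroid score was -1.82 ± 1.50 (SD, n = 4) in Myd88KO infected and -0.56 ± 1.01 in Myd88KO mock spleens (exact permutation p = 0.229, adjusted 0.395). The adipose score was -2.40 ± 1.49 and -0.85 ± 1.31 in these groups (exact permutation p = 0.171, adjusted 0.31).

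The Tlr9 probe was 1.14 (mock, adjusted p = 0.000276) and 1.15 (infected, adjusted p = 0.000103) higher in Tlr7KO than WT, inseparable from slide.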
